A study of Mus musculus with 4 samples.

How the data were processed

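Chromatin bound by FLAG-tagged MIXL1, a paired-type homeodomain protein of the primitive streak, was immunoprecipitated from mouse epiblast stem cells (EpiSC), a cultured pluripotent cell type that corresponds to the epiblast after implantation. Per the labels' protocols, the cells carried an inducible Mixl1 gene, were grown on irradiated mouse fibroblasts with 10 ng/mL bFGF and 20 ng/mL activin A, and were differentiated in serum as embryoid bodies for 2 days, with 1 µg/mL doxycycline over the last 24 h. The series has 4 libraries, of which 2 came from precipitation with the anti-FLAG M2 antibody and 2 were input chromatin. Libraries from cells without doxycycline, or from a mock precipitation, were not analysed here.

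The authors deposited 1 list of peaks for the whole series, with a chromosome, a start and an end for each peak and no score, height or p-value. Per the submitters' processing notes, CASAVA 1.8.2, Bowtie2, SAMtools and MACS2 were used and positions refer to mm10. The peak threshold, the filters, the use of the input libraries and the pooling of the replicates are not given in the sources used here. The libraries therefore enter every result only through this list. Sequencing depth is unknown, no peak can be compared between replicates, and the intervals and p-values cover counting of peaks or sampling of genes, not the spread between cultures.

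Peaks were set against the NCBI RefSeq gene table of GRCm38.p6, the assembly that mm10 denotes. That table gives the span of each gene without strand, transcripts or exons. The design, fixed before the data were examined, called for transcription start sites, and either end of a gene span was used in their place. Exons and introns could not be separated, so peaks were classed by their centre as within 1 kb of an end of a protein-coding gene, otherwise inside a protein-coding gene, otherwise inside another gene only, or outside genes. Genome sequence was not used here, so the planned comparisons of 30 motifs, of half-site spacing and of 8-mers, and all controls matched on GC content, were left out. Chromosome length was taken as the span from 3 Mb to the last annotated gene end, since chromosome lengths without gaps were not used here. Genes listed within the first 3 Mb (340 genes) were left out, because the table also places genes of unplaced scaffolds there. This left 49210 genes, of which 21519 were protein-coding. Positions are printed 1-based.

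Random regions were drawn in 10 sets, each with 1 region per peak on the same chromosome and of the same width, not overlapping a peak. Assembly gaps could not be excluded from them. Shares were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the classes or distances, with 95% Wilson intervals for shares of peaks. Peaks cluster, so these p-values are smaller than independent loci would give.

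For gene lists, each protein-coding gene received a domain of its span plus 5 kb on both sides, extended to the neighbouring genes' spans with their 5 kb, by at most 1000 kb. Neighbouring domains can share peaks. Domains differ in length, and the peak counts given for single genes are not adjusted for it. The number of genes of a list with at least 1 peak in the domain was compared with 10000 random lists of the same size, matched on domain length in 10 bins. The permutation test was two-sided, its smallest possible p is 0.0002, and Benjamini-Hochberg adjustment covered 21 lists with a threshold of 0.05. The lists were fixed before the data were examined and include 4 control lists and 1 list of fibroblast genes for the feeder cells. Fold is the observed number divided by the mean of the random lists. On 20 simulated peak lists over 21519 genes, 0 of 420 list tests without an effect were called after adjustment and 13 had an unadjusted p under 0.05. Simulated peaks were placed at random on the same chromosomes, without the clustering of the real peaks or their closeness to gene ends. False calls that these features could cause were therefore not measured. To plant an effect, 10 genes of the Nodal and Activin list without a simulated peak were marked as near one. That list then passed in 20 of 20 simulations. Marking 200 further regions as lying at gene ends was also recovered in 20 of 20. Effects of other sizes were not examined.

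The rule for named genes was fixed in advance. It takes 13 genes of gastrulation and pluripotency, up to 4 genes with the most peaks from each list that passed, up to 2 from each other list that is not a control, the 10 widest peaks with their nearest protein-coding gene, and the 10 genes with the most peaks. Some genes that the rule takes are not reported here. Width stood in for the missing score. Peak density per chromosome was compared by a chi-square test with 95% Poisson intervals, and clustering by the number of peaks with another peak within 10 kb. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

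The alternatives fixed in advance were the wider 50% of the peaks, genes of every type, a gene-end distance of 5 kb, an extension of at most 100 kb, peaks within 50 kb of the gene span, assignment of each peak to its nearest gene, a binomial test of peaks in domains, clustering within 50 kb, and autosomes only. Added after the data were seen were runs without chromosomes 12 and X, without 1-Mb windows of 20 or more peaks, without predicted genes, and with 200 random sets.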

Results

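The list held 9598 FLAG-MIXL1 peaks from EpiSC-derived embryoid bodies, and 9403 of them lay on the 20 assembled chromosomes that carried a peak. No peak was listed on chromosome Y or the mitochondrial genome. The median width was 487 bp, with quartiles of 350 and 729.75 bp and a maximum of 7566 bp. Peaks covered 5.93 Mb and no 2 of them overlapped. This single list stands for the whole series of 2 FLAG and 2 input libraries, so no value has a replicate error and the depth per library is unknown.

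The first comparison asked which developmental genes had MIXL1 peaks in their neighbourhood. Genes of the Nodal and Activin pathway stood out most by fold among the lists that passed, with 17 of 25 genes near a peak against a mean of 7.72 in random lists of genes with domains of like length (2.20-fold, adjusted permutation p = 0.0042). Primitive streak and mesendoderm genes (14 of 26, 1.90-fold, adjusted permutation p = 0.0189), definitive endoderm genes (19 of 28, 1.79-fold, adjusted permutation p = 0.0070) and Wnt pathway genes (26 of 37, 1.65-fold, adjusted permutation p = 0.0042) were also near peaks more often than matched genes. So were Notch genes (14 of 23, 1.78-fold, adjusted permutation p = 0.0189), paired-type homeobox genes (19 of 32, 1.59-fold, adjusted permutation p = 0.0276), FGF genes (16 of 26, 1.58-fold, adjusted permutation p = 0.0488) and neural ectoderm genes (22 of 30, 1.55-fold, adjusted permutation p = 0.0147). These were 8 of the 21 lists, and no list was near peaks less often than matched genes by this test. Paraxial mesoderm, haemato-endothelial and cardiac genes did not pass. The lists share members, since 23 of the 26 primitive streak genes stand in another list too. The primitive streak list passed under all 8 alternative settings, but with the wider 50% of the peaks it and neural ectoderm were the 2 lists that passed.

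**Figure D1:**
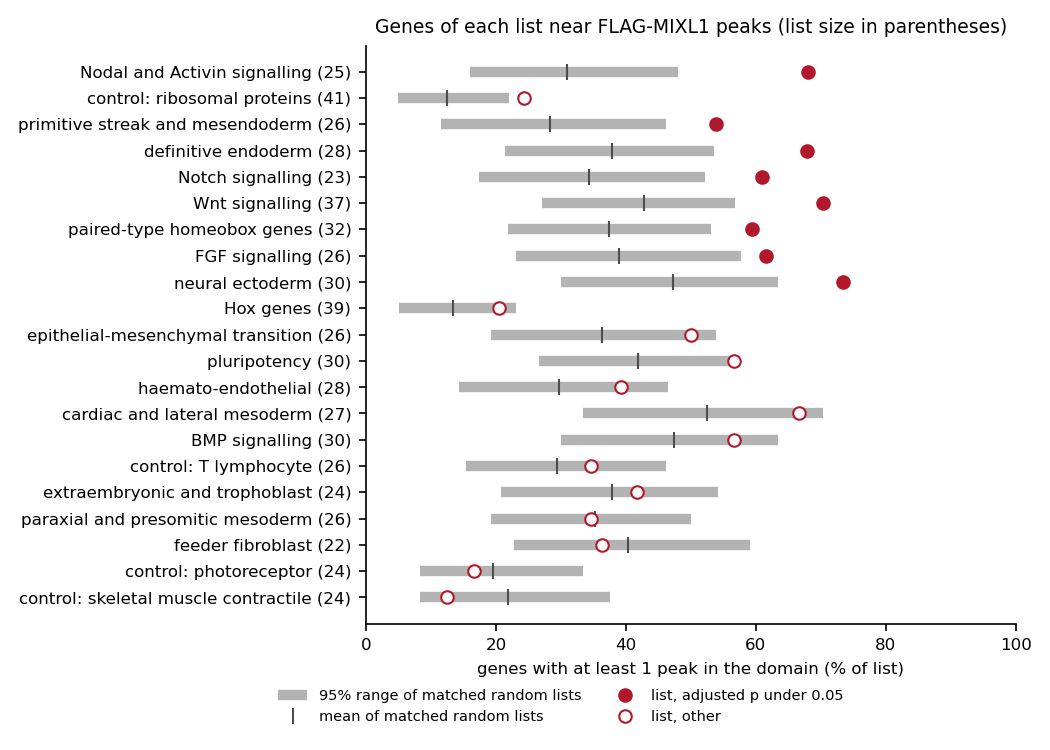
Share of the genes of each list with at least 1 peak in the domain (horizontal axis, percent), with list sizes in parentheses. Grey bars give the 95% range and ticks the mean of 10000 random lists matched on domain length, and filled points mark the 8 lists with an adjusted p under 0.05.

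Among the named genes of the streak and its endoderm, Gsc, Lhx1, Eomes, Foxa2, Sp8 and Cxcr4 had 4 or more peaks each, Mixl1 and Kdr had 1, and T, Sox17 and Mesp1 had none in their domains. Domains differed in length, with 1010 and 846 kb for Foxa2 and Cxcr4 but 354, 90.8 and 18.5 kb for Sox17, T and Mesp1. Within 100 kb, Foxa2 and Cxcr4 had 3 peaks each, Mesp1 had 1, and T and Sox17 had none. Counts of single genes were not tested against domain length. Gsc, a homeobox gene of the organiser (chromosome 12, 104471209 to 104473236), had 13 peaks in its domain, 8 of them within 100 kb and the nearest at 0.462 kb. Lhx1, a LIM-homeodomain gene of the anterior streak (chromosome 11, 84517975 to 84525534), had 8 peaks, the nearest at 9.14 kb. Eomes, a T-box gene required for definitive endoderm (chromosome 9, 118478186 to 118486132), had 5 peaks, of which 1 lay within 1 kb of each gene end, at 118477047 to 118477350 and at 118486909 to 118487335. Foxa2, a forkhead gene of node and endoderm (chromosome 2, 148042877 to 148046969), had 4 peaks and the nearest was 2.00 kb away. Sp8 had 10 peaks and the chemokine receptor gene Cxcr4 had 4. The Mixl1 gene itself (chromosome 1, 180693043 to 180697034) had 1 peak, 6.65 kb beyond its span at 180703455 to 180703910. T (brachyury), Sox17 and Mesp1, genes of early mesoderm and endoderm, had their nearest peaks at 147, 233 and 35.8 kb, while that of Kdr, the receptor gene of early endothelium, was at 35.4 kb. Gsc and Sp8 lie on chromosome 12, where peaks were 3.86-fold denser than on the other autosomes. Gsc also lies in a 1-Mb window of 26 peaks. Without chromosomes 12 and X the primitive streak and definitive endoderm lists still passed, as they did without 1-Mb windows of 20 or more peaks.

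**Figure D2:**
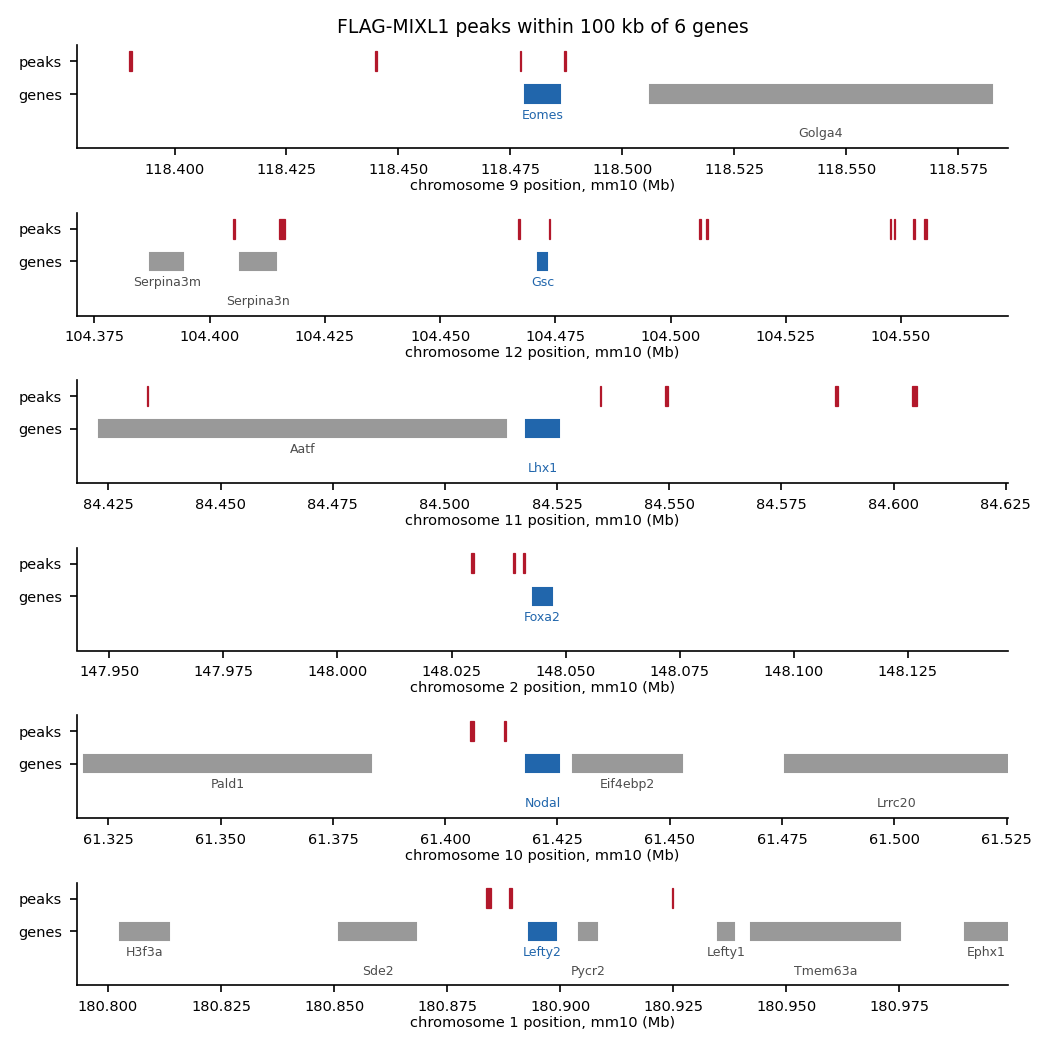
Peaks (red) and protein-coding gene spans (blue for the named gene, grey for neighbours) within 100 kb of Eomes, Gsc, Lhx1, Foxa2, Nodal and Lefty2, drawn to scale on mm10 positions in Mb. The windows hold 4, 10, 5, 3, 2 and 3 peaks in that order, including peaks outside the domain of the named gene.

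Among signalling genes, the Nodal ligand gene (chromosome 10, 61417972 to 61425338) had 2 peaks on one side, at 61405548 to 61406425 and 61413161 to 61413641, the nearer at 4.57 kb. The Nodal co-receptor gene Tdgf1 had 2 peaks with the nearest at 1.48 kb, the Nodal inhibitor gene Lefty2 had 2 with the nearest at 4.00 kb, and Pcsk6, which encodes a convertase of TGF-beta family precursors, had 2 with at least 1 overlapping the gene span. In the Wnt list, Sp8 was followed by Dact1, also on chromosome 12, with 9 peaks, Tcf7l1 with 8 and Tcf7l2 with 6, the latter pair encoding TCF factors that bind beta-catenin. In the FGF list Dusp4 had 12 peaks in a domain of 649 kb, Spred2 8 in 1032.65 kb, Il17rd 6 in 105 kb and Dusp6 5 in 549.6 kb. In the Notch list Maml3 had 9 peaks, Hes1 8, Jag1 5 and Maml2 3. The FGF list lost its call within 50 kb of the gene span (adjusted permutation p = 0.0764), with nearest-gene assignment (0.0602), without chromosomes 12 and X (0.0740) and without predicted genes (0.0695). The Nodal and Activin list passed by genes with a peak but not by number of peaks in its domains (1.26-fold, adjusted p = 0.360, exact binomial test), and the Notch list did not pass with nearest-gene assignment (0.195), the 100 kb extension (0.0602) or without chromosomes 12 and X (0.0588).

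Neural ectoderm genes near peaks were led by En1 with 10 peaks (nearest at 2.02 kb), Pou3f1 and Irx3 with 9 each, and Ncam1 with 8. Within 100 kb, En1 and Irx3 had 4 peaks each, Ncam1 had 2 and Pou3f1 had 1. In the paired-type homeobox list, which holds the family of Mixl1, Gsc had 13 peaks and Pax7 and Pax3 had 4 each, the latter pair with a peak overlapping the gene span. The neural list did not pass within 50 kb of the gene span (1.23-fold, adjusted permutation p = 0.546), with nearest-gene assignment (0.0996) or in the binomial test of peaks (0.0984). The paired-type list did not pass within 50 kb (0.0761), with nearest-gene assignment (0.0602) or without chromosomes 12 and X (0.0612).

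The pluripotency list had 17 of 30 genes near a peak (1.35-fold, adjusted permutation p = 0.230). Esrrb, on chromosome 12 in a 1-Mb window of 49 peaks, had 19 peaks, and Nanog had 2 with the nearest at 4.84 kb. Sox2 had 7 in a domain of 1566 kb, with the nearest at 9.99 kb and only 1 within 100 kb. Pou5f1 had none in its domain of 36.2 kb but 4 within 100 kb. Cardiac and lateral mesoderm genes gave 18 of 27 (1.27-fold, adjusted permutation p = 0.288) with 11 peaks each at Osr1, on chromosome 12, and Msx1. Paraxial mesoderm genes gave 9 of 26 (0.981-fold, adjusted permutation p = 1), with 6 peaks at Epha4 and 4 at Pax3, and haemato-endothelial genes 11 of 28 (1.32-fold, adjusted permutation p = 0.457), with 6 at Cdh5 and 4 at Runx1. BMP genes gave 17 of 30 (1.20-fold, adjusted permutation p = 0.485), led by 18 peaks at Id2 on chromosome 12 and 11 at Msx1. Genes of epithelial-mesenchymal transition gave 13 of 26 (1.38-fold, adjusted permutation p = 0.288), with 4 peaks at Zeb1 and 3 at Fn1. Hox genes gave 8 of 39 (1.54-fold, adjusted permutation p = 0.390), with 3 peaks at Hoxc4, and extraembryonic genes 10 of 24 (1.10-fold, adjusted permutation p = 0.946), with 5 at Eomes and 2 at Apob, on chromosome 12. Fibroblast genes, listed for the feeder cells, gave 8 of 22 (0.902-fold, adjusted permutation p = 0.946), with 5 peaks at Thy1 and 4 at Prrx1. The 4 control lists did not pass: ribosomal protein genes gave 10 of 41 (1.96-fold, adjusted permutation p = 0.0826), muscle contractile genes 3 of 24 (0.573-fold, adjusted permutation p = 0.485), photoreceptor genes 4 of 24 (0.856-fold, adjusted permutation p = 1) and T lymphocyte genes 9 of 26 (1.17-fold, adjusted permutation p = 0.839). Counting peaks by the exact binomial test brought the pluripotency (3.18e-06), BMP (0.000138), Hox (0.00906) and ribosomal control (8.78e-05) lists past the threshold, and Hox genes also passed within 50 kb of the gene span (0.0126). The binomial test treats peaks as independent, but peaks cluster and are denser on chromosome 12, so its p-values are smaller than independent loci would give. Of the 70 pluripotency and 77 BMP peaks it counted, Esrrb and Id2 on chromosome 12 held 19 and 18. The Hox genes lie side by side in a few clusters and can share peaks, so they are not 39 independent observations. Although the ribosomal control did not pass in the main test, its 1.96-fold was exceeded only by the Nodal and Activin list. Its unadjusted permutation p was 0.0354, and its fold was at least 1.52 in all 8 alternatives. Fold alone therefore does not set the developmental lists apart from this control, and the cause of its excess was not tested.

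The second comparison asked where the peaks lay relative to genes. Most MIXL1 peaks lay away from gene ends, yet gene ends held more of them than of random regions. Of the 9403 peaks, 626 (6.66%, 95% interval 6.17 to 7.18) lay within 1 kb of an end of a protein-coding gene, against 3.17% of random regions (odds ratio 2.18, interval 2.00 to 2.38, adjusted p = 1.19e-56, Fisher's exact test). A further 3953 peaks (42.0%) lay inside protein-coding genes, against 38.6% of random regions (odds ratio 1.16, adjusted exact p = 5.05e-11). Another 1247 peaks (13.3%) lay only inside genes of other types, against 8.62% (odds ratio 1.62, adjusted exact p = 1.92e-45). Outside genes were 3577 peaks (38.0%), against 49.6% of random regions (odds ratio 0.623, adjusted exact p = 1.02e-102). The median distance to a gene end was 29.0 kb (interval 27.98 to 30.16), against 48.7 kb for random regions. Peaks lay within 5 kb of a gene end in 17.9% of cases against 12.9% (odds ratio 1.47), within 50 kb in 63.2% against 50.5% (odds ratio 1.68) and within 500 kb in 97.6% against 90.8% (odds ratio 4.06). With genes of every type the median distance was 9.48 kb and the odds ratio within 500 kb was 2.60 (adjusted p = 0.0242, Fisher's exact test). That ratio was 8.83 without chromosomes 12 and X and 7.69 without 1-Mb windows of 20 or more peaks, both chosen after the data were seen.

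**Figure D3:**
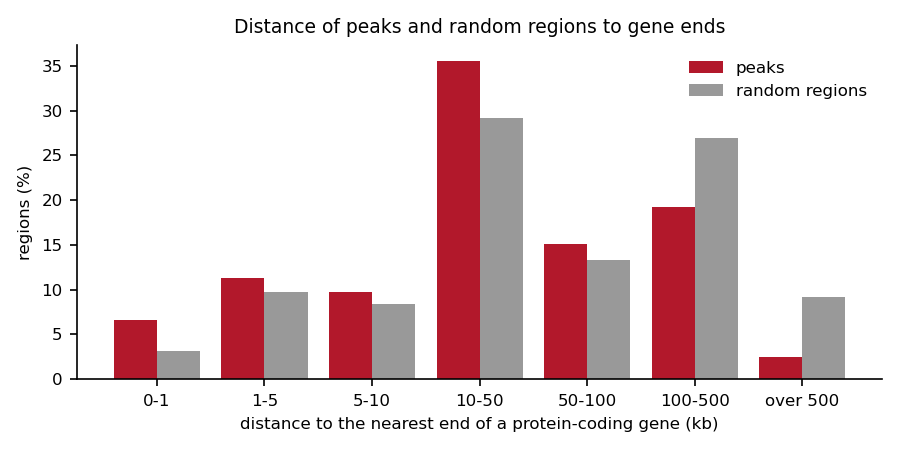
Share of peaks (red) and random regions (grey) in percent, by distance in kb from the centre to the nearest end of a protein-coding gene. Peaks exceed random regions in each bin up to 100 kb and lie below them beyond that.

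Of the 10 widest peaks, 6 lay inside a protein-coding gene and 4 lay 79.4 to 222 kb from one. The widest, of 7566 bp (chromosome 6, 65298089 to 65305654), lay 79.4 kb from Qrfprl, the next 6703 bp inside Pfkp, and those of 6261 bp and 5441 bp lay 211 kb from Khdrbs2 and inside Sik3. The others of the 10 widest were inside Foxn3, Map6, 4930444P10Rik and Ndst3, 222 kb from Igfbp7 and 162 kb from Abhd5. With the list divided by width into 4 equal parts, from the narrowest to the widest part, the share at gene ends was 9.44, 7.53, 6.0 and 3.66%, while chromosome 12 held 14.2, 12.9, 16.6 and 21.8% of the peaks. The median distance to a gene end did not rise throughout, at 23.8, 28.3, 33.3 and 31.4 kb in the same order. Across the 9403 peaks, which are not independent replicates, width and distance to a gene end had a Spearman correlation of 0.0867 (Pearson 0.0955 on log10 values), with a permutation p of 1e-05, the smallest that 100000 permutations can give.

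The third comparison asked whether peaks grouped at loci. Of the 9403 peaks, 2775 (29.5%) had another peak within 10 kb, against 9.75% ± 0.497 (SD over 10 random sets). Within 50 kb the shares were 58.1% and 37.3%. The genes with the most peaks in their domains were Zfp386 on chromosome 12 with 142, Btbd9 and Dnah8 on chromosome 17, on either side of Glo1 and overlapping a stretch of 500 kb with 133 peaks, with 69 and 67, Adam6a on chromosome 12 with 54, and the predicted gene Gm3667 on chromosome 14 with 45. The domains of Zfp386 and Adam6a reach into the immunoglobulin heavy-chain V segments, and 2 and 13 peaks lay within 100 kb of these genes. The next genes were Gm4791 and Rad51b with 39 each, Gm10406 with 30, Gm3248 with 29 and Foxn3 with 27. The permutation p was 0.0909, the smallest that 10 sets can give, and 200 sets, added after the data were seen, gave 0.00498, again the smallest possible. Without 1-Mb windows of 20 or more peaks the share was 21.5% against 9.34%.

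The last comparison set the chromosomes side by side. Chromosome 12 held 1541 peaks, 16.4% of the list on 4.55% of the length searched, or 13.2 peaks per Mb (95% Poisson interval 12.5 to 13.8). The other 18 autosomes together had 3.41 per Mb and ranged from 2.44 to 7.09, with chromosome 17 at the top, so chromosome 12 was 3.86-fold denser (interval 3.66 to 4.08). Chromosome X held 71 peaks, or 0.423 per Mb (interval 0.331 to 0.534), which was 0.124 of the density of the 18 autosomes (interval 0.0969 to 0.157). The densities differed between chromosomes beyond counting error (chi-square 3979.81, 19 degrees of freedom). Among the 2581 windows of 1 Mb, with a median of 2 peaks, 43 held 20 or more, and 22 of these lay on chromosome 12 and 7 on chromosome 17. The immunoglobulin heavy-chain V segments (chromosome 12, 113572929 to 116009954) held 235 peaks, or 96.4 per Mb and 15.2% of the peaks of that chromosome. Without the windows of 20 or more peaks the ratio of chromosome 12 was 2.59 and that of chromosome X 0.136.

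**Figure D4:**
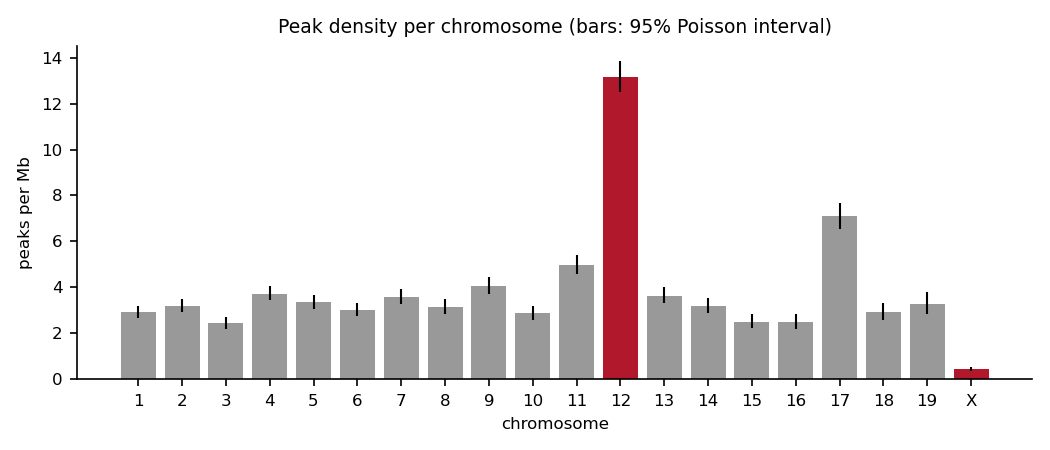
Peaks per Mb of each assembled chromosome, with 95% Poisson intervals as vertical lines. Chromosome 12 at 13.2 and chromosome X at 0.423 (both red) lie outside the range of 2.44 to 7.09 of the other autosomes.

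**Figure D5:**
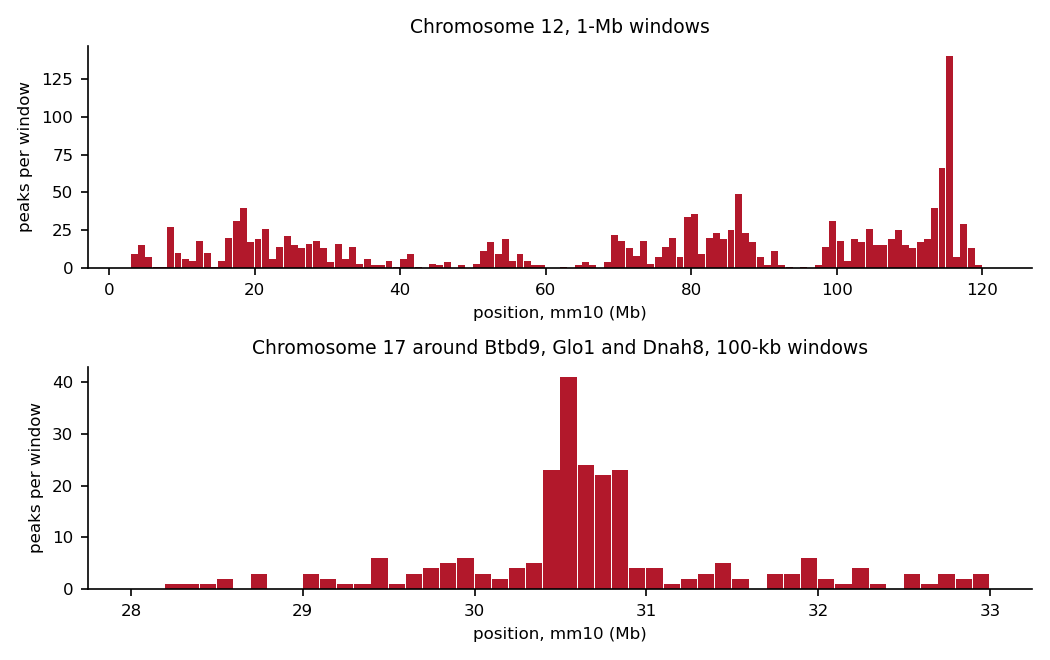
Peaks per 1-Mb window along chromosome 12 (top) and per 100-kb window on part of chromosome 17 (bottom), against position in Mb. The highest chromosome 12 window holds 140 peaks, and on chromosome 17 a run of 5 windows from Btbd9 to Dnah8 holds 133.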

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

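All tests in this part except that of predicted genes in the chromosome 17 block were chosen after the result was seen. The input libraries' coverage, which would show copy number directly, was not analysed here, and no biological explanation was tested.

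The list placed 195 peaks (2.03%) on 16 contigs outside the assembled chromosomes, a signal that no comparison with genes uses. Of these, 153 (78.5%) lay on 4 contigs assigned to chromosome 1, at 235 peaks per Mb of the span they covered, and 42 on the other 12 contigs.

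Chromosome 12 had 3.86-fold more peaks per Mb than the other autosomes. Piling up in dense windows did not account for all of it. Without windows of 20 or more peaks, chromosome 12 kept 767 of its 1541 peaks and the ratio fell to 2.59. Its density was then 8.07 per Mb (interval 7.51 to 8.66) against at most 4.83 on another autosome. Gene density did not account for the excess, since in windows matched on protein-coding genes the ratio was 4.33 (permutation p = 0.0002, the smallest possible) against 0.752 to 2.04 for each other autosome. A gain of the whole chromosome in these cells stays open as a candidate explanation: 3 of 3 equal parts of chromosome 12 were denser than the same part of every other autosome, but the first by a margin within counting error (11.7 against 11.6 per Mb, then 7.90 against 6.20 and 19.9 against 6.13). The 11.6 belongs to chromosome 17, whose first part holds the block described below. The medians of the other autosomes in these parts were 2.89, 2.92 and 3.53 per Mb. Within chromosome 12 the density was uneven. Its median 1-Mb window held 9 peaks, against 2 over all windows. Windows from 57000001 to 69000000 held only 0 to 5 peaks each, and those from 92000001 to 98000000 held 0 to 2. The equal parts average over such stretches, so they cannot show whether the excess runs along the whole chromosome. The size of the excess per copy cannot be read from a list without signal.

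Chromosome X had 0.124 of the autosomal density. Its gene content did not account for this, since the ratio in windows matched on protein-coding genes was 0.141 (permutation p = 0.0002, the smallest possible). A threshold that a single copy of the chromosome passes less often could lower the count and cannot be told apart from other causes here: the median width of the 71 X peaks minus that of the autosomal peaks was -48 bp (permutation p = 0.151). The sex of the cell line was not used here.

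On chromosome 17, 133 peaks lay in 500 kb that cover part of Btbd9 (30215524 to 30582621) and the whole of Glo1 (30592861 to 30612659) and Dnah8 (30626935 to 30875762). Reads shared between copies of a gene family could not be decided on, as 57.1% of 7 genes were predicted or pseudogenes (95% interval 18.4 to 90.1), against a median of 58.8% in random blocks. By the rule written beforehand, a share at or below that median counted against this explanation. Because the interval from 7 genes is wide, the outcome was changed to undecided after the result was seen. An extra copy of this stretch may account for its sharp edges, as the lowest 100-kb window inside held 22 peaks and the highest within 1 Mb outside held 6, but the edges were read from the same counts, so the test cannot decide. Copy-number gains that span Glo1 are known in several inbred mouse strains, and the strain of these cells was not used here.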

How the results depend on the processing

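Runs without chromosomes 12 and X, without dense windows, without predicted genes and with 200 random sets were chosen after the data were seen. Classes of peaks relative to genes, shares within 5, 50 and 500 kb, the chromosome ratios and the correlation of width with distance kept their direction and their side of the threshold in every alternative run, though the odds ratio within 500 kb, 4.06, ranged from 2.60 with genes of every type to 8.83 without chromosomes 12 and X. Of 8 alternatives, the primitive streak list passed in 8, Wnt and definitive endoderm in 7, Nodal and Activin in 6, neural ectoderm in 5, Notch and paired-type in 4 and FGF in 3. One of the alternatives is the binomial test, which treats clustered peaks as independent.

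With the wider 50% of the peaks 2 lists passed, and the folds (adjusted p) were 1.59 (0.236) for definitive endoderm, 2.06 (0.0903) Nodal and Activin, 1.62 (0.102) Wnt, 1.49 (0.375) FGF, 1.57 (0.381) Notch and 1.78 (0.0903) paired-type. Fewer peaks enter here by construction. With nearest-gene assignment 4 lists passed, with 1.45 (0.0996) for neural ectoderm, 1.71 (0.0602) FGF, 1.58 (0.195) Notch and 1.65 (0.0602) paired-type. Without chromosomes 12 and X 5 passed, with 1.55 (0.0740) for FGF, 1.68 (0.0588) Notch and 1.54 (0.0612) paired-type. Within 50 kb of the gene span the values were 1.23 (0.546) for neural ectoderm, 1.57 (0.0764) FGF and 1.51 (0.0761) paired-type. The binomial test gave 1.25 (0.0984) for neural ectoderm and 1.26 (0.360) for Nodal and Activin, the 100 kb extension 1.81 (0.0602) for Notch, and leaving out predicted genes 1.49 (0.0695) for FGF. The cause was not tested. The other 13 lists gave 104 values, of which 99 stayed on their side of the threshold and 5 passed it.

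The median distance to a gene end was 32.6 kb for the wider 50%, 26.4 kb without chromosomes 12 and X and 9.48 kb with genes of every type. The clustering ratio of 3.03 was 3.06 with 200 sets (permutation p = 0.00498), which allow a lower p by construction.

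No paired analysis was possible because the libraries' replicate numbers do not appear in the single list, and for the same reason leaving out a library was not possible. Motif, spacing and 8-mer alternatives and controls matched on GC content were not run. Depth is unknown, so peaks missed at low depth are not known.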

Other observations

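The search over gene families by symbol was chosen after the data were seen, and it covered 274 symbol stems of 10 or more genes.

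Among the clustered protocadherins, adhesion proteins of neurons, 12 of 12 Pcdhga genes (4.55 in random lists, adjusted permutation p = 0.0137) and 12 of 12 Pcdha genes (6.04, adjusted permutation p = 0.0274) were near peaks, more than genes with domains of like length, but 0 of 22 Pcdhb genes were (1.39, adjusted permutation p = 1). The Pcdhga genes overlap one another and share the same peaks, as do the Pcdha genes, so each of these families is closer to 1 observation than to 12. Genes with the stem Atp, a mixed group of ATPases and ATP synthase subunits, gave 40 of 85 (25.5, adjusted permutation p = 0.0219). Receptor families of the olfactory system were near peaks less often, with 39 of 1109 olfactory receptor genes (168, adjusted permutation p = 0.0137) and 29 of 352 vomeronasal receptor genes (101, adjusted permutation p = 0.0137). Random lists draw genes singly from the whole genome, so where members of a family lie side by side these p-values are smaller than independent loci would give. Btbd genes gave 4 of 42 (18.8, adjusted permutation p = 0.0137), but 29 of the 42 lie on chromosome X, which had few peaks at all. Without chromosomes 12 and X the Btbd genes gave 4 of 11 (3.37, adjusted permutation p = 1) and the Pcdha genes missed the threshold (12 of 12, 6.30, adjusted permutation p = 0.0651), while the other 4 families were called again. That setting added 2 families with fewer genes near peaks, Pramel with 2 of 44 (10.4, adjusted permutation p = 0.0405) and Serpinb with 2 of 28 (9.22, adjusted permutation p = 0.0422). The 6 families called with all peaks were also called without dense windows.

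Outside chromosomes 12 and 17, dense windows included 51 peaks between 6 and 7 Mb of chromosome 14, where 97.1% of genes were predicted or pseudogenes, 43 peaks from 66 Mb of chromosome 13 (91.3%), 37 from 171 Mb of chromosome 1 (19.2%) and 37 from 93 Mb of chromosome 3 (52.8%).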
